A study of Mus musculus with 11 samples.

How the data were processed

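Chromatin accessibility was measured by ATAC-seq in dentate gyrus of 8-week-old C57BL/6 mice that had received an adeno-associated virus (AAV) with a control shRNA or an shRNA against c-Fos. Per the labels' protocols, each library came from an individual mouse. The submitters' processing notes name Bowtie2, a read aligner, and the mouse genome build mm9. How reads were filtered or shifted for the transposase, and with which settings peaks were called, is not given in the sources used here.

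The deposited values are 11 lists of peaks, 1 per library, each with a chromosome, a start, an end, a peak name and a score. The peak names carry the name of the peak caller MACS. Per the deposited lists, the score runs from 50 to 3100 in every library. That range resembles the caller's transformed p-value, but no header or label states the scale, so the score was used only to rank peaks within a list and for 1 minimum. Read depth per library is unknown, and a longer list can come from deeper sequencing as well as from more open chromatin. The lists held 498212 peaks in all, from 25215 to 78377 per library, a 3.11-fold range. The deposited names of 9 of the 11 lists carry an added word that the other 2, shRNA-Ctrl E1 replicates 1 and 3, lack. Its meaning is not given in the sources used here.

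Peaks on chromosomes 1 to 19 and X were used, which left out 554 peaks. Peaks of all 11 lists that shared at least 1 bp were merged into regions, and a region was called in a library that had a peak in it. A region counted as found only in 1 group when every library of that group and no library of the other called it. Within a comparison single regions were not tested, since 3 libraries against 3, or 3 against 2, allow no exact p under 0.1. A test of single regions for E1 against E0 over all 11 libraries, stratified by shRNA, was added after seeing the data, as were counts with 2 libraries on each side where groups had 2 and 3. The counts were compared with those from every other split of the same libraries into groups of the same sizes. They were also compared with a model of list length alone, chosen after seeing the data, that keeps the number of libraries calling each region and the share of calls of each library. The model takes any real excess of calls in a group into its shares, so it tests how well groups separate, not which group has more regions.

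Peak numbers were compared on the log2 scale by two-sided exact permutation tests. Labels for E0 and E1 were permuted within shRNA groups, and shRNA labels within E0 and E1, with Benjamini-Hochberg adjustment over 7 tests. Regions found only at E1 in 1 shRNA group were read in the libraries of the other shRNA group. The share called was set against that of matched regions, called in as many libraries of the first group but in another combination. Similarity of lists was the base-pair Jaccard index, the length in both lists divided by the length in either, tested by one-sided exact permutation. Wilson 95% intervals of shares cover counting error only.

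The regions named by position, in mm9 coordinates, follow a rule fixed before the data were examined. They are the 10 per comparison and direction with the highest mean within-list score percentile, of which the text names some, and the 5 windows of 100 kb with most regions found only at shRNA-Ctrl E1. Alternatives fixed at the same time were a score of at least 100, covered length in place of peak number, every list shortened to the 25145 highest-scoring peaks, and all chromosomes. Others were 50% of a region covered, peaks within 200 bp merged, a call missing from at most 1 library, the replicate number as a block, and each library left out in turn.

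The annotation at hand was of build GRCm38, and peaks lay beyond its last gene on 10 of 20 chromosomes. Coordinates were not moved between builds, so regions carry no gene names. The comparisons of fixed gene lists and of the AP-1 motif, planned for the case that an mm9 annotation and sequence were at hand, were not run. The merging and the calls were tested on simulated lists for the comparison of shRNA-Ctrl E1 with shRNA-Ctrl E0. All 200 planted regions were recovered among 128823, and the stratified permutation test passed 4.5% of 400 simulated data sets with no effect. Simulated peaks of different regions could not overlap and planted calls were complete. That recovery therefore checks the code and not how well regions are found in real lists. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.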

Results

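ATAC-seq marks accessible DNA by the insertion of sequencing adapters with a transposase, and a peak is a stretch where insertions accumulate. Accessibility was profiled in the dentate gyrus, the hippocampal field of granule neurons, in a study of how neuronal activation changes chromatin. Mice carried an AAV with a control shRNA (shRNA-Ctrl) or an shRNA against c-Fos (shRNA-cFos), a subunit of the transcription factor AP-1 whose gene responds rapidly to neuronal activity. The labels give the states E0, whose deposited lists are named as sham, and E1. The groups were shRNA-Ctrl E0 (3 libraries), shRNA-Ctrl E1 (3), shRNA-cFos E0 (3) and shRNA-cFos E1 (2). The lists show where chromatin was called open and not how far c-Fos was reduced.

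The 11 lists merged into 128823 regions covering 81.5 Mb. Of these, 11796 (9.16%) were called in all 11 libraries and had a median width of 1363 bp. Another 48877 (37.9%) were called in 1 library only, with a median width of 340 bp. With every list shortened to its 25145 highest-scoring peaks there were 59298 regions, of which 9716 were called in all 11 libraries.

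The number of peaks on chromosomes 1 to 19 and X was 27685 ± 2271 (SD, n = 3) in shRNA-Ctrl E0 and 63244 ± 24080 (n = 3) in shRNA-Ctrl E1. It was 45328 ± 25315 (n = 3) in shRNA-cFos E0 and 44445 ± 5399 (n = 2) in shRNA-cFos E1. All 3 shRNA-Ctrl E1 lists were longer than all 3 shRNA-Ctrl E0 lists, a mean difference of 1.11 on the log2 scale (2.16-fold; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow; adjusted p = 0.338). In shRNA-cFos the difference was 0.10 on the log2 scale (exact p = 1), while the arithmetic mean at E1 lay slightly below that at E0. Over both shRNA groups E1 lists were 1.52-fold longer, which did not pass the test (log2 difference 0.61, exact permutation p = 0.14, adjusted p = 0.338). Without shRNA-cFos E0 replicate 2, whose list held 74432 peaks against 28417 and 33134 in its group, the log2 difference was 0.82 (exact p = 0.0167). Between shRNA groups the peak number differed by 0.08 on the log2 scale (exact permutation p = 0.86). The E1 effect in shRNA-cFos minus that in shRNA-Ctrl was -1.0 (exact p = 0.145), and -1.38 (exact p = 0.0333) without shRNA-Ctrl E1 replicate 2, the shortest list of its group. That leave-out keeps in shRNA-Ctrl E1 only the lists whose names lack the added word, so the 2 cannot be told apart. Without shRNA-cFos E0 replicate 2 the difference of effects shrank instead. The E1 effect and this difference of effects each had 15 alternatives. For each, only the leave-out given with its exact p had an exact permutation p under 0.05.

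**Figure D1:**
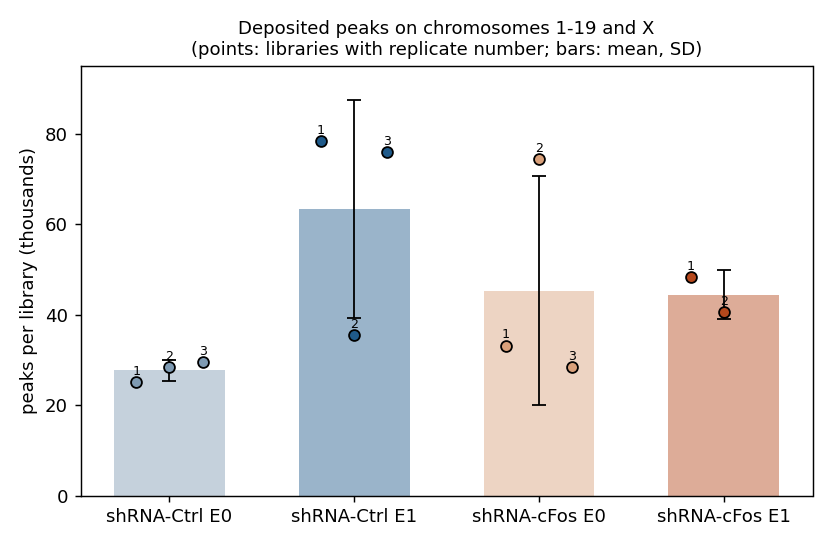
Peaks per library on chromosomes 1 to 19 and X for the 4 groups. Points are libraries with their replicate numbers, bars are group means and whiskers are SD; shRNA-Ctrl E1 replicate 2 (35474) lies far below replicates 1 (78349) and 3 (75908), and shRNA-cFos E0 replicate 2 (74432) far above the other E0 libraries.

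The first comparison asks which chromatin differs between E1 and E0 with the control shRNA. In shRNA-Ctrl dentate gyrus, 7779 regions were called in all 3 E1 libraries and in none of the 3 E0 libraries, and 57 showed the opposite pattern. With lists of equal length, 2080 regions were found only at E1 and 683 only at E0, so E1-only regions outnumbered E0-only regions 3.05 to 1. The E1-only region with the highest scores lay on chromosome 4 at 64903223 to 64904595 (mean score percentile 99.0). Next came chromosome 2 at 138380652 to 138381646, chromosome 18 at 15480217 to 15481322, chromosome 13 at 36683545 to 36684514 and chromosome 6 at 22495938 to 22496926. The other 5 of the 10 by rule lay on chromosomes 16, 19, 19, 3 and 10, and the lowest mean percentile of the 10 was 94.6.

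All 10 of these regions were also called in both shRNA-cFos E1 libraries. In shRNA-cFos E0, 6 of the 10 were called in all 3 libraries, 1 in 2 libraries and 3 in 1 library. At equal list length the chromosome 2 region was called in all 5 E1 libraries and in none of the 6 E0 libraries. The E0-only region with the highest scores as deposited lay on chromosome X at 72329441 to 72330506 (mean percentile 56.6). At equal list length the highest mean percentiles were 97.4 for E1-only and 80.9 for E0-only regions, the latter on chromosome 14 at 7469317 to 7470195. The chromosome X region was called in all 3 shRNA-cFos E0 libraries and in neither shRNA-cFos E1 library. Next came chromosome 16 at 96502182 to 96503112, called in all 6 E0 libraries and in 1 shRNA-cFos E1 library.

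E1-only regions were spread over many loci. The 7779 regions fell into 6085 of 23244 windows of 100 kb that held any region. The window with most lay on chromosome 8 at 93800001 to 93900000, with 6 E1-only regions among 11, of which 3 were called in both shRNA-cFos E1 libraries. Windows with 5 lay on chromosome 10 at 94200001 to 94300000, chromosome 14 at 67700001 to 67800000, chromosome 18 at 65200001 to 65300000 and chromosome 3 at 108600001 to 108700000. Among lists of equal length, the window on chromosome 13 at 37300001 to 37400000 held most, 4 of 5 regions, and 3 of the 4 were called in both shRNA-cFos E1 libraries.

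**Figure D2:**
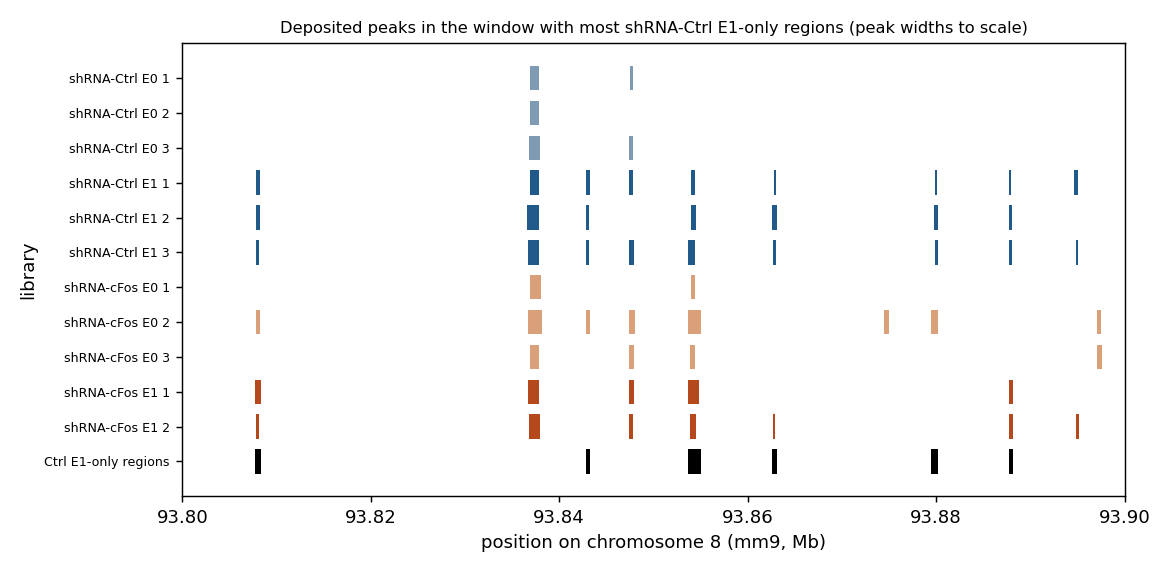
Deposited peaks in each of the 11 libraries across the chromosome 8 window at 93800001 to 93900000 (mm9, in Mb), 1 row per library, with peak widths to scale. Black bars in the lowest row are the 6 regions called in all 3 shRNA-Ctrl E1 libraries and in no shRNA-Ctrl E0 library; shRNA-cFos E0 replicate 2 also has peaks in 4 of them.

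Of the 10 splits of the 6 shRNA-Ctrl libraries, the real one gave the highest count in either direction, 7836 regions against at most 2391 in another split. The list-length model gave 5135 E1-only regions and 3.55 E0-only regions. With lists of equal length the counts were 2763 against at most 486, and the model gave 451 E1-only and 153 E0-only regions. Leaving out shRNA-Ctrl E1 replicate 2 raised the E1-only count to 24144. Leaving out any 1 library raised the E0-only count to between 97 and 197, since fewer libraries then have to call a region or to lack it.

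The next comparison asks the same with c-Fos targeted. In shRNA-cFos dentate gyrus, 2522 regions were called in both E1 libraries and in none of the 3 E0 libraries, and 706 showed the opposite pattern. At equal list length the counts were 2012 and 911, where the list-length model gave 854 and 308. Fewer calls suffice in the group of 2, so the pairs of counts are not balanced. With 2 libraries on each side and lists of equal length, E1-only regions were 1.32 to 1.67 times as many as E0-only regions over the 3 choices of E0 libraries, and 0.833 to 9.05 times as deposited. The highest-scoring E1-only regions lay on chromosome 14 at 88965120 to 88966003 (mean percentile 93.4), chromosome 18 at 22030805 to 22031930, chromosome 18 at 34399092 to 34400593 and chromosome 4 at 81843169 to 81843919. All 10 by rule were called in all 3 shRNA-Ctrl E1 libraries, and 6 of them in no E0 library. The highest-scoring E0-only region, on chromosome 4 at 42961263 to 42963957 (2695 bp, mean percentile 86.8), was called in all 6 shRNA-Ctrl libraries as well, so the 2 shRNA-cFos E1 libraries were the only ones without it. The next, on chromosome 2 at 54755361 to 54756027, was called in the 3 shRNA-cFos E0 libraries and in no other.

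As deposited, the real split gave 3228 regions in either direction, fewer than the 5340 for shRNA-cFos E0 replicate 2 with E1 replicate 1 against the rest. Among lists of equal length the real split gave the highest count of 10, 2923 against at most 1549. Leaving out shRNA-cFos E0 replicate 2 raised the E1-only count to 7580, and leaving out E1 replicate 1 or 2 raised it to 5749 or 8722. The E0-only count rose to 2310 and 3156 without E0 replicates 1 and 3, and to 1859 and 1329 without E1 replicates 1 and 2. The direction turned without E0 replicate 3, with 2627 E1-only against 3156 E0-only regions.

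Whether the chromatin that distinguished E1 in 1 shRNA group also did so in the other was read in libraries that had no part in choosing the regions. The shRNA-Ctrl E1-only regions were called far more often in shRNA-cFos E1 than in shRNA-cFos E0 when lists had equal length. Of the 2080 regions, shRNA-cFos E1 replicates 1 and 2 called 73.9% (95% interval 72.0 to 75.7) and 65.4% (63.3 to 67.4). The 3 shRNA-cFos E0 libraries called 23.0%, 20.3% and 16.5%. Matched regions were called at 44.5% ± 0.958 (SD, n = 2) in E1 and 45.4% ± 2.5 (n = 3) in E0. Both shRNA-cFos E1 libraries called 1176 of the 2080 (56.5%), 1 of them called 545, and neither called 359 (17.3%).

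As deposited, the E1 libraries called 74.3% and 60.1% of the 7779 regions, and the E0 libraries 21.4%, 57.3% and 14.2%. Net of matched regions, E1 libraries lay 38.6 percentage points above E0 libraries (two-sided exact permutation p = 0.1, the smallest that 2 against 3 allow), and 50.6 points above with lists of equal length. The shRNA-cFos E1-only regions, read in shRNA-Ctrl with lists of equal length, were called at 64.3% ± 4.28 (SD, n = 3) in E1 and 13.1% ± 2.12 (n = 3) in E0. That net difference was 59.5 points, and 38.7 points as deposited (exact p = 0.1 for each). Matched regions of shRNA-cFos could be those called in a pair of E0 libraries. At equal length they were called at 24.4% in shRNA-Ctrl E1 and 32.6% in shRNA-Ctrl E0, so the net difference exceeds the 51.3 points without matching. The E0-only regions of shRNA-Ctrl were called at 58.6% ± 3.49 (n = 3) in shRNA-cFos E0 and 32.9% ± 4.66 (n = 2) in shRNA-cFos E1 with lists of equal length (exact p = 0.1), and at 62.6% and 50.9% as deposited (exact p = 0.3). Those of shRNA-cFos were called at 50.4% in shRNA-Ctrl E0 and 24.0% in shRNA-Ctrl E1 with lists of equal length (exact p = 0.1), but as deposited at 32.1% and 48.2%, in the opposite direction (exact p = 0.4).

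**Figure D3:**
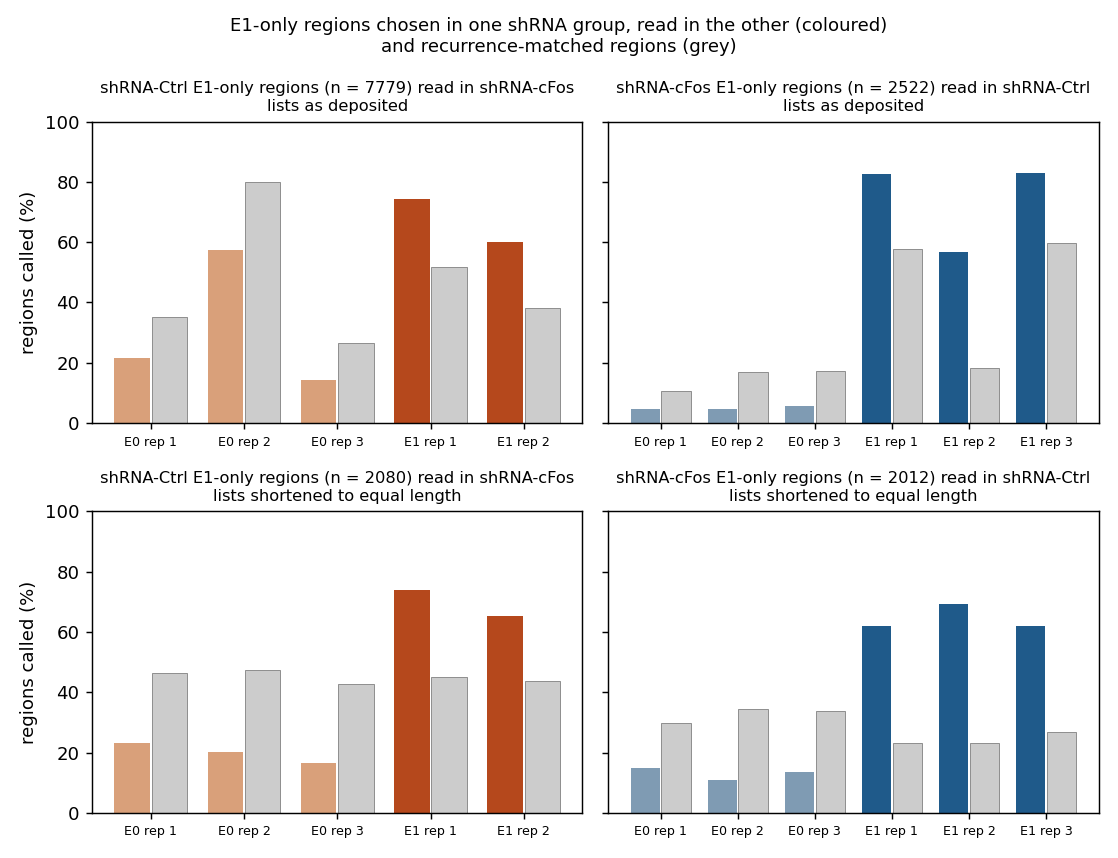
Percent of E1-only regions chosen in 1 shRNA group that each library of the other group called (coloured bars), beside matched regions (grey bars), with lists as deposited (top) and of equal length (bottom). With equal lengths every E1 library stands above its matched regions and every E0 library below, for example 73.9% and 23.0% in shRNA-cFos E1 and E0 replicate 1.

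The sets overlapped in the same direction. With lists of equal length, 571 regions were called in all 5 E1 libraries and in none of the 6 E0 libraries, where independent lists would share 70.6. The E0-only sets shared 63 regions against 10.5 for independent lists. In opposite directions the sets shared 3 and 2 regions, against 32.0 and 23.2. As deposited, 1104 regions were called in all 5 E1 and in no E0 library, and 3 the other way round. No single region passed a stratified exact permutation test of E1 against E0 over all 11 libraries after Benjamini-Hochberg adjustment. The smallest adjusted p was 0.468 at equal length. The smallest p this permutation test allows is 0.005, which 634 of 59298 regions reached. Adjustment over so many regions needs far more of them at that floor, so the test could hardly pass any. An unadjusted permutation p under 0.05 was found for 2254 of 59298 regions, and for 4519 of 128823 as deposited. These shares cannot be set against 0.05, since many regions could not reach such a p. At equal length 32.9% of regions were called in 1 library only and 16.4% in all 11, and neither kind can pass.

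The knockdown comparison at E0 asks what the c-Fos shRNA changes in the sham state. As deposited, 1430 regions were called in all 3 shRNA-cFos E0 libraries and in no shRNA-Ctrl E0 library, and 28 showed the opposite pattern. At equal list length the counts were 569 and 248. The highest-scoring regions found in shRNA-cFos E0 and not in shRNA-Ctrl E0 lay on chromosome 12 at 63732743 to 63733658 (mean percentile 89.3), chromosome 18 at 50987592 to 50989162 and chromosome 10 at 96954948 to 96955920. The last 2 were also called in all 5 E1 libraries. The highest-scoring in the opposite direction lay on chromosome 2 at 69964708 to 69965312 (mean percentile 48.0).

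The real split of these 6 libraries gave 1458 regions in either direction and another split gave 1191. Among lists of equal length these were 817 and 559, and the model of list length gave 332 and 154 regions where 569 and 248 were found. The 1430 regions became 2298 and 2378 without shRNA-Ctrl E0 replicates 2 and 3, and 3746 and 5367 without shRNA-cFos E0 replicates 1 and 3. The 28 regions became between 43 and 352 with any 1 library left out, the last without shRNA-cFos E0 replicate 2.

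The knockdown comparison at E1 asks which E1 regions differ when c-Fos is targeted, and its balance depended on list length and on the libraries used. As deposited, 2048 regions were called in all 3 shRNA-Ctrl E1 libraries and in neither shRNA-cFos E1 library, and 688 the other way round. With lists of equal length the counts were 638 and 1009, where the list-length model gave 399 and 703, since fewer calls suffice in the group of 2. With 2 libraries on each side, regions only in shRNA-Ctrl E1 were 1.79 to 16.8 times as many as regions only in shRNA-cFos E1 as deposited, and 0.756 to 1.07 times at equal length, over the 3 choices of shRNA-Ctrl libraries. The highest-scoring region found in shRNA-Ctrl E1 and not in shRNA-cFos E1 lay on chromosome 6 at 47630663 to 47637092, a merged region of 6430 bp. It was also called in 2 shRNA-Ctrl E0 libraries and 1 shRNA-cFos E0 library. Regions on chromosome 15 at 66829792 to 66830520, chromosome 10 at 23289093 to 23289758 and chromosome 1 at 79361981 to 79362584 were called in the 3 shRNA-Ctrl E1 libraries and in no other. The rest of the 10 by rule were also called in 1 to 6 E0 libraries. In the opposite direction, the region on chromosome 5 at 110833868 to 110835265 (mean percentile 79.7) scored highest, and the region on chromosome 1 at 80734092 to 80734923 was called in the 2 shRNA-cFos E1 libraries alone. Apart from that last region, the 10 in this direction were also called in 1 to 4 E0 libraries.

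As deposited, the split of shRNA-Ctrl E1 replicates 1 and 3 against the other 3 libraries gave 12611 regions in either direction and the real split 2736. At equal list length the same split gave 2166 and the real one 1647. Without shRNA-Ctrl E1 replicate 2 the 2048 regions became 14491, and without shRNA-cFos E1 replicates 1 and 2 they became 5176 and 3116. The 688 regions became 1332 and 1531 without shRNA-Ctrl E1 replicates 1 and 3, and 3452 and 3992 without shRNA-cFos E1 replicates 1 and 2. Without shRNA-cFos E1 replicate 2, which leaves 1 library against 3, 3992 regions were found only in shRNA-cFos E1 and 3116 only in shRNA-Ctrl E1.

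Lists of the same state resembled each other more than lists of different states within a shRNA group. The mean Jaccard index was 0.440 within groups and 0.378 between E0 and E1 (one-sided exact permutation p = 0.04), and 0.505 and 0.45 with lists of equal length (exact p = 0.02). Between shRNA groups of the same state it was 0.430 (exact p = 0.26), and 0.488 with lists of equal length (exact p = 0.09). The highest index of any pair was 0.540, between the shRNA-cFos E1 libraries. The lowest was 0.250, between 2 lists of the same state, shRNA-Ctrl E0 replicate 1 and shRNA-cFos E0 replicate 2. That pair was also the lowest with lists of equal length (0.383). The difference between states also lost its call with a score of at least 100 (exact p = 0.06) and with the replicate number as a block (exact p = 0.125). It lost its call without any single library but shRNA-cFos E0 replicate 2, with exact p from 0.05 to 0.08, and lay at 0.094 (exact p = 0.0333) without that library.

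**Figure D4:**
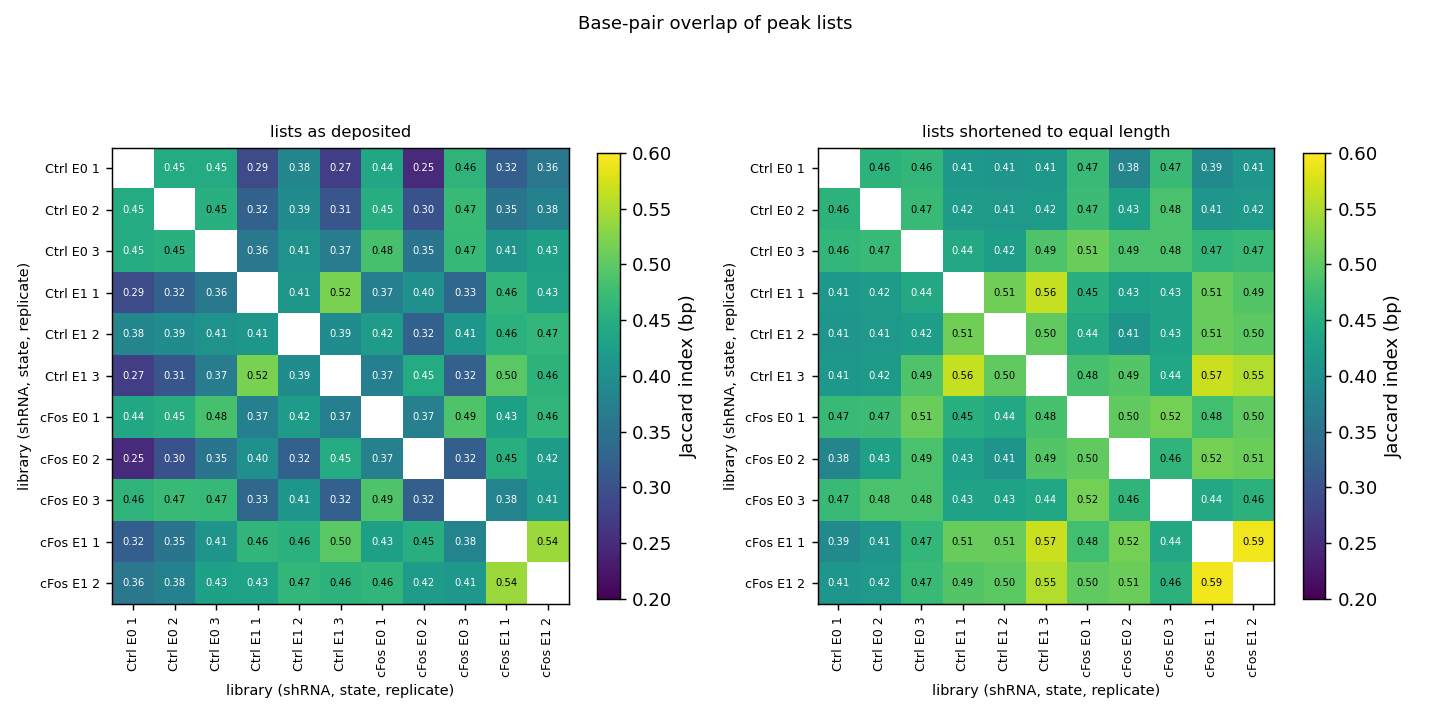
Base-pair Jaccard index of each pair of the 11 lists, as deposited (left) and with lists of equal length (right). With equal lengths the 4 highest values, up to 0.591, all join E1 lists.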

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

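Chosen after seeing the data were the tests of list length, of the added word in the list names, of the 3 longest lists left out, of held-out regions, of gaps between shRNA groups and of 2 libraries on each side, and the counts over other splits of 6 libraries.

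Chromosome Y, used only in the alternative with all chromosomes, held peaks in every library, from 28 in shRNA-Ctrl E1 replicate 1 to 70 in shRNA-Ctrl E0 replicate 1.

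In shRNA-Ctrl, more regions were called only at E1 (7779) than only at E0 (57). With lists of equal length the ratio of E1-only to E0-only regions was still 3.05. That ratio cannot decide on list length, since the list-length model then also split unevenly, with 451 E1-only and 153 E0-only regions. The model takes any real excess of calls into its shares, so it does not show which ratio length alone gives. The counts found, 2080 and 683, were 4.61 and 4.45 times those of the model. Closer agreement between deeper libraries stays open: without the 3 longest lists the ratio was at least 2.54 at equal length, but the E1 lists left (1 of shRNA-Ctrl, 2 of shRNA-cFos; 35474 to 48262 peaks) were all still longer than the E0 lists left (25145 to 33134). For the missing word in 2 shRNA-Ctrl E1 list names, replicate 2, which has the word, was examined. Its net share of shRNA-cFos E1-only regions lay 44.1 points above the highest shRNA-Ctrl E0 library. A higher share at E1 thus did not rest on those 2 lists alone. That share does not show how far the 2 lists make the excess of E1-only regions, so the missing word stays open for the excess. A difference in accessibility between E1 and E0 may underlie part of the excess. It cannot be told apart from list length, from closer agreement between deeper libraries or from the difference in list names here. A batch of preparation was not tested.

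More regions were called only in shRNA-Ctrl E1 (2048) than only in shRNA-cFos E1 (688). List length is a candidate explanation, since with lists of equal length and 2 libraries on each side the ratio of the former to the latter was at most 1.07 over the 3 choices, against at least 1.79 as deposited. A smaller E1 response under shRNA-cFos stays open. For a held-out share, regions were chosen that 1 E1 library of each shRNA group called and 1 E0 library of each lacked. They were read in the libraries left over. The share called in shRNA-cFos E1 minus that in shRNA-Ctrl E1 was -1.67 points at equal length and -11.4 points as deposited. Choosing those regions required a call in a shRNA-cFos E1 library, so regions lost there were never counted. Whether some E1 regions did not open under shRNA-cFos cannot be told apart from chance either, since the gap between own and other shRNA group was 5.69 points wider for regions chosen in shRNA-Ctrl E1, with ranges that overlap (0.457 to 10.7 against -2.58 to 4.78; exact permutation p = 0.3, where 0.1 is the smallest possible) at equal length, while as deposited it was 27.4 points with ranges apart (exact p = 0.1).

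Regions found only at E1 in 1 shRNA group were called more often at E1 in the other. List length alone would give E1 and E0 libraries the same share once lists are equally long. Net of matched regions the shRNA-cFos libraries still differed by 50.6 points, with an SD of 1.91 among the E0 libraries. Shortening equalised the number of peaks and not read depth. The lowest score kept was 50 in shRNA-Ctrl E0 replicate 1 and 175 in shRNA-Ctrl E1 replicate 3. In shRNA-cFos E0 replicate 2, the longest shRNA-cFos list, it was 162, and that library called 20.3% of the shRNA-Ctrl E1-only regions. A shared set of regions that are more accessible at E1 with either shRNA may account for the difference between E1 and E0 libraries, as a hypothesis. Which of these regions bind AP-1, and how far c-Fos was reduced, was not analysed here.

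For the 6 shRNA-Ctrl libraries, the real split was the 1 of 10 with a count as large (7836, highest other 2391), and for the 6 E0 libraries it was also 1 of 10 (1458, highest other 1191). Such splits are too few for a share under 0.05. For regions called in all 5 E1 and in none of the 6 E0 libraries or the reverse, with lists of equal length, 1 of 100 arrangements drawn gave as many (634, highest other 141), which excludes a chance arrangement of states within shRNA groups at 0.05.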

How the results depend on the processing

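Directions of the net shares of E1-only regions read across shRNA groups and of the E1 effect on peak number held under all alternatives run for them, and counts depended on list length and on how many libraries had to call a region. In each set below the comparisons run in the order shRNA-Ctrl E1 against shRNA-Ctrl E0, shRNA-cFos E1 against shRNA-cFos E0, shRNA-cFos E0 against shRNA-Ctrl E0 and shRNA-cFos E1 against shRNA-Ctrl E1, with the count for the first group before that for the second. With a score of at least 100 the counts were 4229 and 16, 1282 and 224, 628 and 7, and 295 and 774, which follows from fewer peaks, and the similarity difference by state was 0.0692 (exact p = 0.06). With equal list lengths they were 2080 and 683, 2012 and 911, 569 and 248, and 1009 and 638. Groups of 2 and 3 do not split evenly without an effect, and the list-length model gives 703 and 399 for the last pair. With lists shortened only to the shortest of the libraries compared, an alternative chosen after seeing the data, the last pair was 1496 and 955. With 50% of a region covered, regions only in shRNA-cFos E1 and not in shRNA-Ctrl E1 numbered 1821, above the 1556 in the opposite direction; the cause was not tested. With a call allowed to be missing from 1 library the counts were 26238 and 428, 2522 and 4888, 7826 and 380, and 688 and 15811, by construction, since groups of 2 kept the full requirement; the second pair turned its direction.

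Same-numbered libraries did not deviate together (correlations from -0.0424 to 0.0505), so the numbers were not taken as pairs. With the replicate number as a block, which leaves out shRNA-cFos E0 and shRNA-Ctrl E1 replicate 3 in comparisons with shRNA-cFos E1, shRNA-cFos had 2628 E1-only and 3156 E0-only regions, its direction turned, and the counts of shRNA-cFos E1 against shRNA-Ctrl E1 were 1527 and 2740. The similarity difference of 0.0619 then had an exact p of 0.125, and no other call changed.

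With each library left out, the counts ranged from 8803 to 24144 and from 97 to 197, from 2627 to 8722 and from 841 to 3156, from 1580 to 5367 and from 43 to 352, and from 861 to 3992 and from 2680 to 14491, as fewer libraries then had to call a region or to lack it. The direction turned without shRNA-cFos E0 replicate 3 in the second comparison (2627 and 3156) and without shRNA-cFos E1 replicate 2 in the last (3992 and 3116, 1 library against 3). The similarity difference by state ranged from 0.0423 to 0.0939, and that by shRNA from -0.00325 (without shRNA-Ctrl E0 replicate 1) to 0.0276. The log2 difference in peak number between E1 and E0 ranged from 0.47 to 0.82, and that between shRNA groups from -0.14 to 0.21 (-0.11 without shRNA-Ctrl E1 replicate 2, -0.14 without shRNA-cFos E0 replicate 2). The difference of the E1 effects ranged from -1.38 (without shRNA-Ctrl E1 replicate 2) to -0.58 (without shRNA-cFos E0 replicate 2). The cause was not tested.

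Chosen after seeing the data, the 9 libraries with the added word gave 11952 and 1518 for the first comparison and 7736 and 5148 for the last, with 1 shRNA-Ctrl E1 library left. Leaving the 3 longest lists out gave 12039 and 1526, 7600 and 842, 1584 and 352, and 7768 and 5192. Both left 2 libraries against 1 in the last comparison. With 2 libraries on each side the medians over 3 choices were 2840 and 2309 for the second comparison and 1331 and 2740 for the last, and with equal lengths as well 2645 and 1827, and 1629 and 1232. The fixed gene lists and the AP-1 motif were not run, for lack of an annotation and sequence of build mm9. Read depth is unknown, so a region missing from a short list may lie below its detection limit; equal lengths took 2048 regions to 638 in the last comparison.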

Other observations

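The tests of how E1-only regions lie to each other and to regions called in all libraries were set before their results were seen; the chromosome shares were looked at with no test planned.

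Neighbourhoods: with lists of equal length, 2.02% of the 2080 shRNA-Ctrl E1-only regions had another within 10 kb, against 0.865% to 3.70% in 1000 random sets of regions called in as many libraries. In shRNA-cFos it was 2.24% (random median 2.19%). The hypothesis that E1 opens neighbourhoods rather than single sites was not borne out at equal list length. As deposited, the shares were 9.42% in shRNA-Ctrl and 4.2% in shRNA-cFos, inside the random ranges (up to 9.68% and 4.28%) but reached by only 16 and 3 of 1000 random sets. The median distance of the 2080 regions to the nearest region called in all 11 libraries was 85273 bp (random median 78824 bp), which 11 of 1000 random sets reached; it lay inside the range set beforehand as the bound, but that bound was too wide to exclude a value so near its upper end. As deposited, the distance was 62961 bp, which 511 of 1000 reached. For shRNA-cFos E1-only regions it was 78432 bp at equal length (random median 79327 bp). As deposited it was 58351 bp there, below the lowest random value of 58356 bp. It stays open whether shRNA-Ctrl E1-only regions lie away from constitutively open chromatin, and those of shRNA-cFos did not.

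By chromosome, E0-only regions were sparse on chromosome 19 in both shRNA groups with lists of equal length, with 4 regions in shRNA-Ctrl (0.586%, random median 1.76%) and 6 in shRNA-cFos (0.659%, random median 1.87%). In shRNA-cFos, 58 E1-only regions lay there (2.88%, highest random value 2.78%), and in shRNA-Ctrl 31 (1.49%, random median 1.88%). Chromosome X held 37 of the 683 shRNA-Ctrl E0-only regions (5.42%, highest random value 5.27%) but 22 of the 911 shRNA-cFos E0-only regions (2.41%, random median 2.96%). It held 37 of the shRNA-cFos E1-only regions (1.84%, equal to the lowest random value). As deposited, chromosome X held 9 of the 57 shRNA-Ctrl E0-only regions (15.8%, highest random value 10.5%), and chromosome 18 held 422 of the shRNA-Ctrl E1-only regions (5.42%, highest random value 5.05%). Chromosome 17 held 4.08% of shRNA-cFos E1-only regions, as 1 of 1000 random sets did, and chromosome 1 held 7.02%, below the lowest random value of 7.14%. Chromosomes 7 and 19 held 5 shRNA-cFos E0-only regions each (0.708%), below and equal to the lowest random values of 1.27% and 0.708%. Every value that at most 1 of 1000 random sets reached is among those given, out of 20 chromosomes in each of 4 sets and both kinds of list, with no adjustment.

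The median peak width was 510 ± 72.5 bp (SD, n = 3) in shRNA-Ctrl E0, 447 ± 72.1 (n = 3) in shRNA-Ctrl E1, 529 ± 9.71 (n = 3) in shRNA-cFos E0 and 591 ± 3.54 (n = 2) in shRNA-cFos E1, and none of 7 exact permutation tests passed 0.05. Those between single groups allow no p under 0.1, so they could not pass. The comparison of shRNA-cFos E1 with shRNA-cFos E0 reached that bound (exact permutation p = 0.1).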
